A study of Mus musculus with 42 samples.

How the data were processed

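The data are 42 peak lists, 1 per library, from chromatin immunoprecipitation and sequencing of mouse CD8-positive dendritic cells. The antibodies were against the coactivator p300, acetylated histone H4 (H4ac) and the transcription factors PU.1, IRF8, IRF3, IRF5, cREL and JUNB, and input chromatin was sequenced beside them. Cells were left unstimulated (UT) or received the class B oligonucleotide CpG, a ligand of TLR9, or poly(I:C) (pIC), a double-stranded RNA analogue sensed by TLR3 and by cytosolic helicases. p300, H4ac, PU.1, IRF8 and input have 2 libraries per stimulus, and IRF3, IRF5, cREL and JUNB have 1. The labels do not say whether replicates came from separate animals or cultures. The labels name the spleen as the source and also speak of a cell line, and this was left as it stands.

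Per the submitters' processing notes, BWA 0.7.10, SAMtools 0.1.19, HOMER 4.2 and MACS2 (no version given) were used with the genome build mm10, without the role or order of each tool. Per the file headers and the peak names, the peaks were called by MACS in all lists except H4ac, which holds windows from HOMER, and every list was annotated with HOMER. The median width of the H4ac windows was 1001 bp in every list. The deposited score of each peak is the authors' own, with no unit stated, and was used only to rank peaks within 1 list. Numbers inside the MACS peak names run past the number of peaks kept, so peaks were removed before deposit. The missing numbers made up 43.3 to 46.3% in the input lists, 40.1% in the list labelled JUNB pIC and 1.01 to 4.08% in the other MACS lists. The distance to the transcription start site (TSS), the nearest gene and the annotation class are those of the deposited lists. Peak lists do not state a read depth, so the depth of each library is unknown, and Wilson intervals at the 95% level cover counting error only.

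The labels disagree in places. The stimulation time is 90 min in the protocol and runs from 90 up to 103 min across the pIC libraries in the sample characteristics. The pIC dose is 5 µg/ml in one place and 5 mg/ml in another, and CpG is given as 1 mM. The peak names inside 4 of the 6 cREL and JUNB lists give another antibody or stimulus than the label, so each is called the library labelled with its name and no stimuli were compared for them. Groups for all other libraries follow the labels.

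Peaks on chromosomes 1 to 19, X and Y were kept. For each antibody, peaks of all its libraries that overlapped by at least 1 bp were merged into regions. A region counted as gained when called in both stimulated libraries and in neither unstimulated library, and as lost in the reverse case. CpG and pIC were also compared directly in the same way. Beside each count stand the counts from the other ways to split the same 4 libraries into 2 against 2, as a measure of differences between libraries. IRF3 and IRF5 have 1 library per stimulus, so their gained regions have no replicate check. The number of peaks per library was compared by an exact permutation test, two-sided, whose smallest possible p with 2 libraries against 2 is 0.333, so no call was possible. Overlap between the regions gained after CpG and after pIC stands beside the number from independent lists and beside the mean of 100 simulated sets of unchanged libraries.

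A gene was tied to a region when the deposited annotation named it as nearest and the distance to its TSS was at most 20 kb. The number of genes of 15 fixed lists tied to each set was ranked among 10000 random lists of the same size from 20290 annotated genes. The random genes were matched on the number of unstimulated PU.1 and IRF8 regions per gene (0, 1, 2, or 3 and more). The highest class held 9560 of the 20290 genes, so genes with many regions were not told apart. Random genes were drawn singly, so neighbouring genes within a list may raise its fold, for every antibody. A list was said to stand apart above the 99th percentile, which describes these libraries and is not a p-value. The lists were antiviral interferon-stimulated genes, type I interferon and IRF3-dependent primary genes, inflammatory NF-kB genes, negative feedback regulators, dendritic cell maturation and costimulation, cDC1 identity genes, myeloid lineage factors and targets, antigen presentation, immediate early and AP-1 genes, Toll-like receptor signalling, housekeeping genes, T and B cell markers, macrophage, monocyte and neutrophil markers, pDC and cDC2 markers, and genes of non-haematopoietic tissues. Symbols were looked up through the RefSeq gene table of the same build. Unmatched symbols were 1 antiviral gene (Ifi44l), 1 inflammatory gene (Csf3), 6 T and B cell markers and 7 genes of other tissues.

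Named genes were chosen by a rule fixed before the data were examined. It took at most 4 genes per list, antibody and set with the highest mean score percentile over the libraries that called the region, at most 10 genes outside the lists by the same percentile, and 20 fixed genes in every library. The tests, lists and groups were also fixed at that point, as were most alternatives. The closing part names the exceptions.

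Alternatives were overlap of at least 50% of the shorter peak, the upper 50% of each list by score, lists shortened to equal length, removal of peaks that overlap input peaks, distances of 5 kb and 100 kb, random lists without matching, each library left out in turn, and same-numbered libraries as a block. Alternatives added after seeing the data were matching on regions of the antibody itself in any library (classes 0 to 10 and more, a count that includes the tested regions), removal of peaks annotated as low-complexity or simple repeats, and each library left out for further results. The motif analysis that was planned was not run, since no genome sequence was at hand.

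Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and bedtools 2.31.1 were used. The steps were tested on simulated data. Of 200 regions planted as gained after CpG among the 22747 p300 regions, 82% were found, where 81% were expected to be drawn into both libraries. In the same run 636 regions that were not planted were also called gained, so the rule alone does not separate changed from unchanged regions. Of 500 random lists tested against the p300 regions gained after pIC, 2 passed the 99th percentile among 20290 genes. Of 500 lists drawn with 3 times the odds of a hit, 278 (55.6%) did. Overlap counts for p300 and IRF3 peaks after pIC differed from those of bedtools by 0.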

Results

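The 42 libraries map p300, H4ac, PU.1, IRF8, IRF3, IRF5, cREL and JUNB in CD8-positive dendritic cells left unstimulated or stimulated with CpG or pIC, with 14 libraries per stimulus, input included. All positions are in the mouse build mm10, and the depth behind each list is unknown. Peaks of p300 numbered 13262 ± 628 after CpG, 13170 ± 640 after pIC and 12029 ± 3748 in unstimulated cells (SD, n = 2 each). H4ac windows numbered 12087 ± 761, 12710 ± 20.5 and 14976 ± 1257 in the same order. PU.1 gave 69097 ± 5397, 74598 ± 3951 and 53057 ± 31478 peaks, and IRF8 gave 54186 ± 388, 55724 ± 17.7 and 58218 ± 8645. The unstimulated PU.1 libraries differed most, with 30799 and 75315 peaks. IRF3, with a single library per stimulus, gave 20939 peaks after CpG, 36090 after pIC and 16088 in unstimulated cells, and IRF5 gave 49568, 51469 and 32638. Input libraries gave 290 to 344 peaks. No difference in peak number between stimuli of a replicated antibody could be called, since the exact permutation p was 0.333 or higher in every comparison and 0.333 is the smallest it can be.

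**Figure D1:**
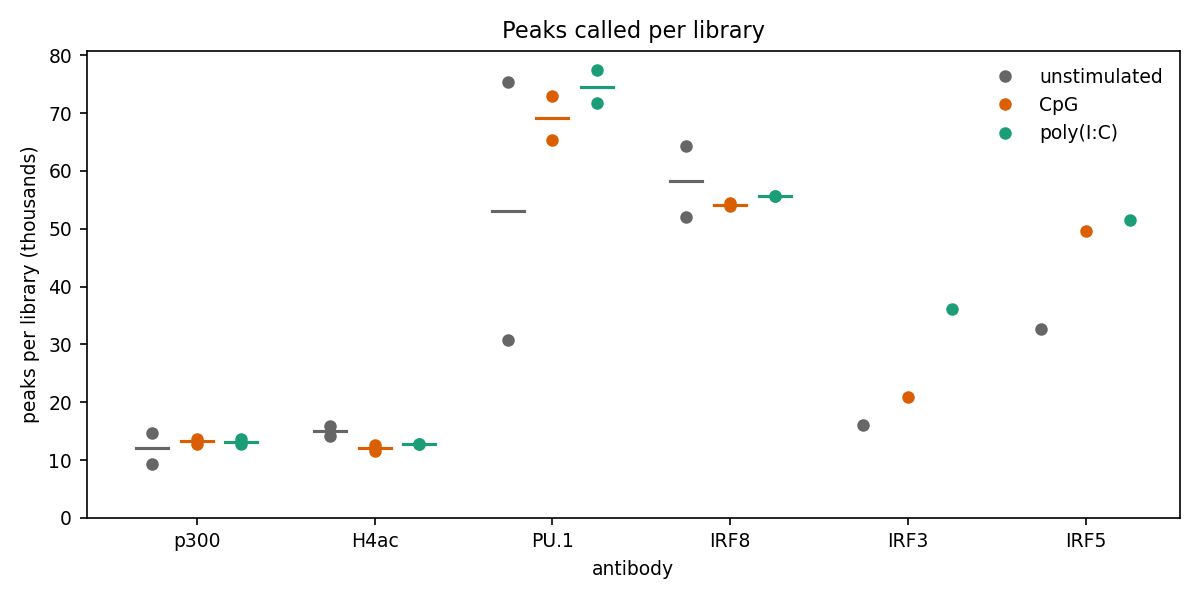
Peaks per library (vertical axis) for 6 antibodies, with 1 point per library and a line at the mean of 2 replicates. The unstimulated PU.1 replicates lie at 30799 and 75315 peaks, and IRF3 rises from 16088 in unstimulated cells to 36090 after pIC.

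The first comparison asks where p300, a histone acetyltransferase recruited to active enhancers, appeared after CpG. New p300 regions lay at inflammatory genes. Il1b, an inflammatory cytokine, had 6 and 7 p300 peaks within 20 kb in the CpG libraries and 1 in each unstimulated library. Il12b, a subunit of the T cell polarising cytokine IL-12, had 5 in each CpG library and 1 in each unstimulated library. Il6 had 5 and 6 against 2 and 3. In total 2125 regions were gained and 793 lost, and the sum of 2918 stood against at most 803 in the mixed splits of the same libraries. With lists of equal length the lost percent of the regions of the compared libraries moved from 4.03 to 8.17.

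Of the inflammatory NF-kB genes, 26 of 63 had a gained p300 region, 5.88 times the mean of random lists and above the 99th percentile. The highest score percentiles belonged to Il1b (chromosome 2, 129385318 to 129385781, intergenic, -14420 bp from the TSS, percentile 93.1), the cytokine gene Lta (chromosome 17, 35209945 to 35210713, intergenic, -4906 bp, 92.2), the anti-inflammatory cytokine gene Il10 (chromosome 1, 131037951 to 131038592, intergenic, 18399 bp, 92.2) and the stress response gene Gadd45b (chromosome 10, 80930413 to 80930891, intron, 484 bp, 91.5). Maturation and costimulation genes followed with 10 of 36 (3.78 times), led by the activation marker Cd83 (chromosome 13, 43775060 to 43775649, intergenic, -9718 bp, 87.9), the adenosine receptor gene Adora2a (percentile 76.7), the inhibitory ligand gene Cd274 (64.4) and Cd200 (62.6). Type I interferon and IRF3-dependent primary genes reached 6 of 21 (4.93 times), with the cytokine gene Il27 (chromosome 7, 126595831 to 126596272, -1130 bp, 88.9), the receptor gene Il15ra (83.3), the chemokine gene Ccl5 at its promoter (chromosome 11, 83530456 to 83530890, -129 bp, 64.9) and Peli1 (58.1). Myeloid lineage genes (11 of 34, 3.87 times), cDC1 identity genes (8 of 32, 2.77 times) and immediate early genes (7 of 26, 3.20 times) also stood apart. These folds may in part reflect the number of regions near a gene, since the main matching puts 9560 of 20290 genes in its highest class. Matching on p300 regions per gene counts the tested regions too and, over the antibodies, lowered 71 of 72 list folds, so a call lost under it was not read as absence of an excess. The inflammatory list kept its call under it at 1.83 times. The calls of the interferon (1.77), maturation (2.01), myeloid (1.43) and immediate early genes (1.28) ended, and cDC1 genes fell to 0.911. Within 5 kb of the TSS cDC1 genes turned to 0.668. The maturation list also missed the threshold within 5 kb of the TSS (2.95), and the immediate early list within 100 kb (2.20). Without unstimulated replicate 1 the interferon, maturation and myeloid folds were 3.28, 2.37 and 2.40.

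Antiviral genes did not stand apart after CpG, with 11 of 81 (1.97 times, percentile 97.9). Those with the highest ranked regions were Mnda (57.2), the RNA sensor gene Ifih1 at its promoter (48.2), the guanylate-binding protein gene Gbp5 (47.5) and the membrane restriction factor gene Ifitm3 (44.3). Within 5 kb of the TSS, and without matching, the same list passed the threshold at 2.76 and 2.92 times, as it did without CpG replicate 1 (2.19) and without unstimulated replicate 1 (1.82). Outside the lists, the leading regions lay nearest to Fam89a (chromosome 8, 124756213 to 124757188, percentile 99.2), D10Jhu81e (99.2) and Gm16793 (98.9), and the leading Hmgb2 and Tspyl3 regions were 65707 and 26706 bp from the TSS.

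The second comparison asks where p300 appeared after pIC. Ifnb1, which encodes interferon beta, had 4 p300 peaks within 20 kb in each pIC library against 1 and 0 in unstimulated cells, and Isg15, an interferon-induced ubiquitin-like modifier, had 1 in each pIC library and 0 in both unstimulated libraries. Ccl5 had 6 and 7 against 2 and 0. Il1b had 6 and 7 against 1 and 1. In total 2803 regions were gained and 1352 lost (4155, against at most 645 in mixed splits), and with lists of equal length the lost percent of regions moved from 6.57 to 11.05.

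Antiviral genes stood apart after pIC with 23 of 81 (3.35 times). The leading regions were at promoters of Ifih1 (chromosome 2, 62646065 to 62646467, -5 bp, percentile 93.9), the antiviral GTPase gene Mx2 (chromosome 16, 97534911 to 97535432, -899 bp, 92.9) and Isg15 (chromosome 4, 156200630 to 156201130, -62 bp, 88.6), and in an intron of the ADP-ribosyltransferase gene Parp14 (chromosome 16, 35869081 to 35869578, 2053 bp, 90.9). Of the type I interferon and primary genes, 10 of 21 gained p300 (6.64 times), led by Il27 (chromosome 7, 126597538 to 126598210, -2896 bp, 98.4), the Ifnb1 promoter (chromosome 4, 88522681 to 88523159, -97 bp, 94.7) and the Ccl5 promoter (-129 bp, 91.2). Inflammatory genes were again among them with 26 of 63 (4.81 times), led by Lta (94.0), Il1a (chromosome 2, 129319863 to 129320542, -10190 bp, 93.0), the histamine-forming enzyme gene Hdc (87.5) and the Il6 promoter (chromosome 5, 30012640 to 30013377, 38 bp, 80.3). Maturation genes reached 9 of 36 (2.82 times), with Tnfsf15 (96.4) and the lymph node homing receptor gene Ccr7 (chromosome 11, 99167961 to 99168469, -13110 bp, 83.5), and feedback regulators 7 of 28 (2.86 times). Matched on p300 regions per gene, antiviral, interferon and inflammatory lists kept their calls at 2.16, 2.61 and 1.73 times, and maturation genes (1.56) and feedback regulators (1.21) did not. Both of the latter calls also missed the threshold within 5 kb, at folds no lower (3.06 and 3.19). The maturation call ended with lists of equal length (1.97), and the feedback call when low-complexity and simple repeats were removed (2.57) or pIC replicate 2 was left out (2.35). Outside the lists the leading regions were at Srsf12 (chromosome 4, 33228371 to 33229062, intron, 19722 bp, percentile 99.9), Nrf1 (99.9), Lipe (99.8), Popdc2 (99.8) and Rilpl2 (99.7).

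**Figure D2:**
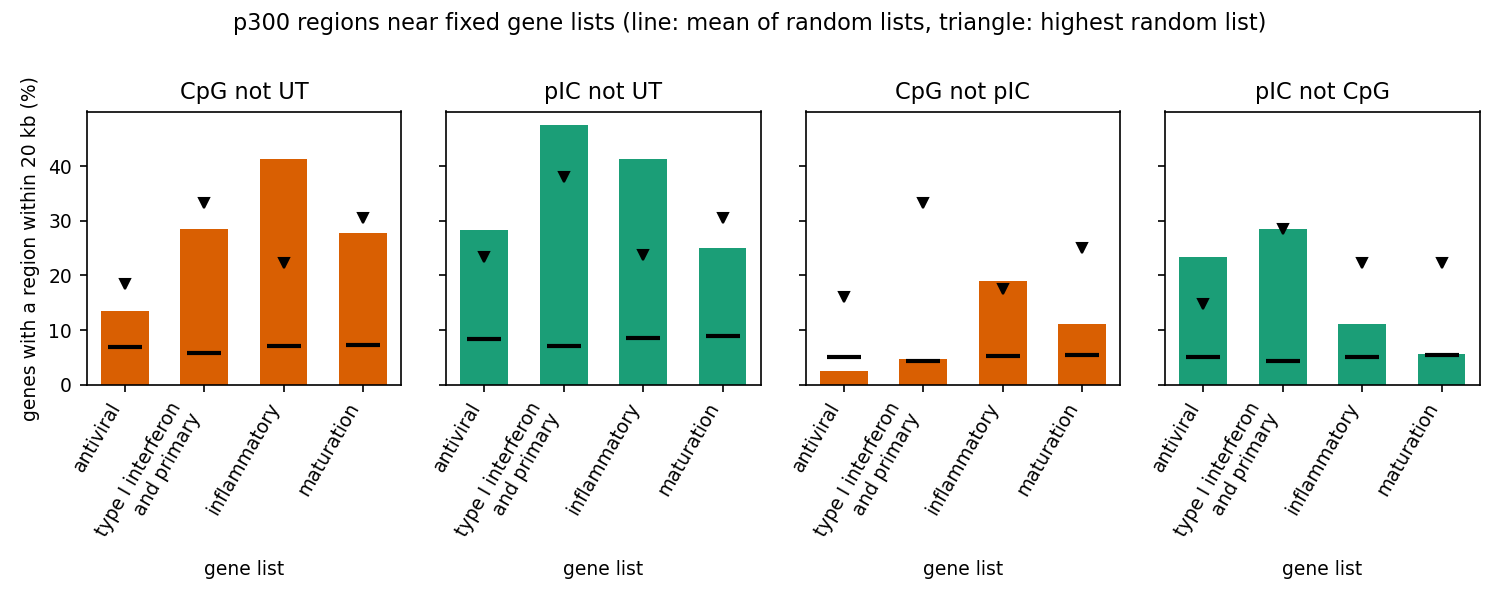
Percent of the genes of 4 lists with a p300 region within 20 kb of the TSS (bars), for 4 sets of p300 regions, with the mean (line) and highest (triangle) of 10000 random lists. After pIC and not CpG 23.5% of antiviral genes had a region, and after CpG and not pIC 2.47%.

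The third comparison sets CpG directly against pIC for p300, without the unstimulated libraries. Isg15, Mx2 and Parp14 were among the genes with p300 regions after pIC and not CpG, and Saa3, Il12b and Rel among those of the reverse set. A gene of either set can hold other p300 regions after both stimuli. Near Il12b, both pIC libraries also had p300 peaks absent from unstimulated cells, such as 44398841 to 44399201 on chromosome 11 (pIC replicate 1). Regions called in both CpG and neither pIC library numbered 1454, and 1694 showed the reverse, against at most 552 in mixed splits for the sum of 3148. Antiviral genes lay near pIC regions in 19 of 81 cases (4.60 times) and near CpG regions in 2 (0.485 times). Without pIC replicate 1 the first fold was 3.04, and the second was 0.745 without CpG replicate 1 and 0.807 without pIC replicate 2. Mx2 (chromosome 16, 97535676 to 97536221, promoter, -133 bp, percentile 93.1), Parp14 (90.9), Isg15 (88.6) and the helicase gene Ddx60 at its promoter (chromosome 8, 61927836 to 61928412, 17 bp, 86.0) led the antiviral genes. Interferon and primary genes with pIC regions numbered 6 of 21 (6.58 times, or 3.96 without pIC replicate 2), led by Isg15, Ifna2 (chromosome 4, 88680462 to 88680859, 3104 bp, 85.6), Ccl5 (chromosome 11, 83540932 to 83541306, -10591 bp, 72.2) and Ifit3 (chromosome 19, 34569820 to 34570394, intron, -13376 bp, 70.8). CpG regions lay near 1 of these 21, Peli1.

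Regions called after CpG and not pIC lay near 12 of 63 inflammatory genes (3.67 times), led by the acute phase gene Saa3 (chromosome 7, 46716969 to 46717339, -1472 bp, percentile 87.3), the NF-kB subunit gene Rel (chromosome 11, 23778644 to 23779360, -7940 bp, 80.6), Il12b (chromosome 11, 44389928 to 44390464, -9867 bp, 78.5) and Il6 (chromosome 5, 29994434 to 29994798, -18545 bp, 72.8). Regions called after pIC and not CpG lay near 7 of 63 (2.15 times, percentile 96.1), including the kinase gene Irak2 (50.7), the apoptosis regulator gene Cflar (41.2), Il1b (32.0) and Vcam1 (25.1), and this list passed the threshold without matching (3.07 times) and without CpG replicate 1 (2.45) or 2 (2.41), but fell to 0.841 times when matched on p300 regions per gene. Matched on p300 regions per gene, the antiviral list with pIC regions kept its call at 2.93 times, and the inflammatory call with CpG regions ended at 1.17 times. The interferon call with pIC regions ended at 2.71 times, and within 5 kb it missed the threshold narrowly at a fold of 6.91 (percentile 98.99). CpG regions also lay near 9 of 34 myeloid genes (4.24 times) and 7 of 33 Toll-like receptor signalling genes (3.96 times), and both calls ended under that matching (1.53 and 1.95 times). Without CpG replicate 2 the myeloid fold was 2.68, and the Toll-like receptor call ended at 2.31. Myeloid genes also stood apart near p300 regions called in unstimulated and not pIC libraries (3.21 times). That call ended within 5 kb (2.77) and when matched on p300 regions per gene (1.25). The direct comparison thus does not separate gain after CpG from loss after pIC.

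**Figure D3:**
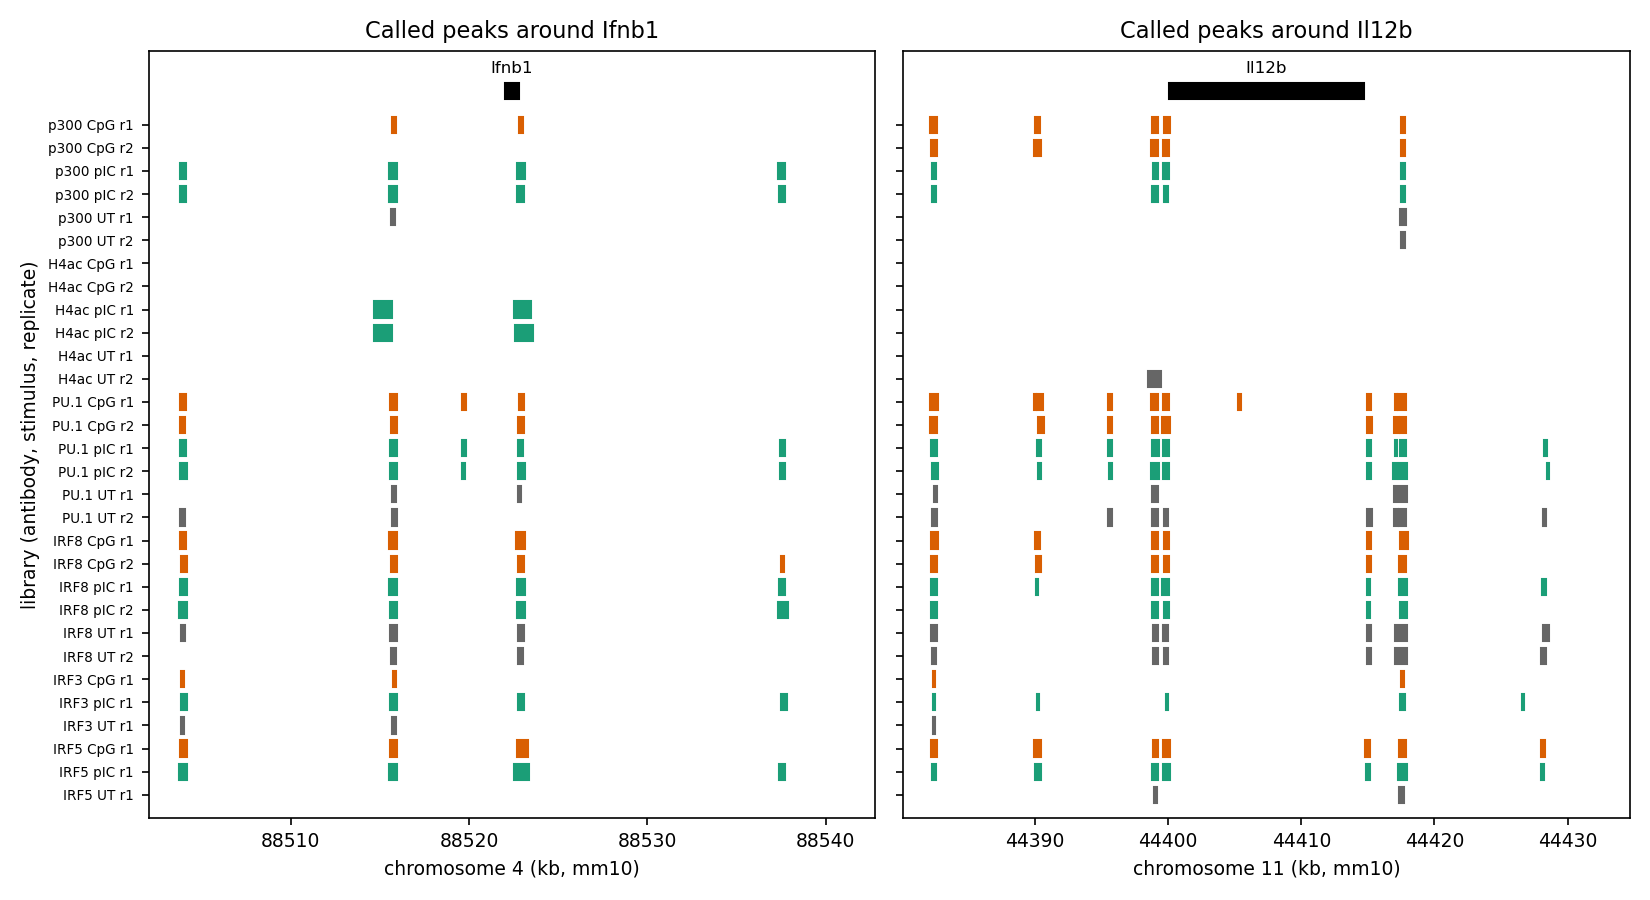
Called peaks of each library (1 line per library) from 20 kb before to 20 kb after Ifnb1 on chromosome 4 and Il12b on chromosome 11, in kb of mm10, with CpG in orange, pIC in green and unstimulated cells in grey. Both pIC libraries of p300 have 4 peaks at Ifnb1 against 1 and 0 in unstimulated cells. Both CpG libraries of p300 have 5 at Il12b, and both pIC libraries also have p300 peaks there that unstimulated cells lack.

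The gained sets after CpG and pIC were also set against each other. For p300, 1027 regions were gained after both stimuli, 48.3% of those gained after CpG. Independent lists drawn from all 22747 p300 regions would share 262. Such a number is too low by construction for each antibody, since regions called in unstimulated cells cannot be gained. Simulated unchanged libraries, whose gained sets were smaller (695 and 683 regions on average, against 2125 and 2803), shared 161. For H4ac the shared number was 462, against 47.9 from independent lists and 46.7 in the simulation, whose sets held 302 and 334 regions. For PU.1 it was 2182 (243, and 1222 in simulated sets of 3332 and 3920), and for IRF8 617 (32.2, and 220 in sets of 1112 and 1174). The numbers from the simulation belong to its smaller sets, so neither baseline measures an excess. Both stimuli were compared with the same 2 unstimulated libraries, and a split with 1 unstimulated library for each stimulus was not run. Part or all of the overlap above independent lists may come from these shared controls. IRF3 and IRF5 shared 5630 and 21009 gained regions, against 3988 and 11604 from independent lists. A single unstimulated library stood behind both of their contrasts, and no simulation was run for them. With lists of equal length the percent of regions gained after both moved from 2.21 to 4.99 for H4ac, from 0.792 to 1.24 for IRF8 and from 14.5 to 6.44 for IRF3.

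**Figure D4:**
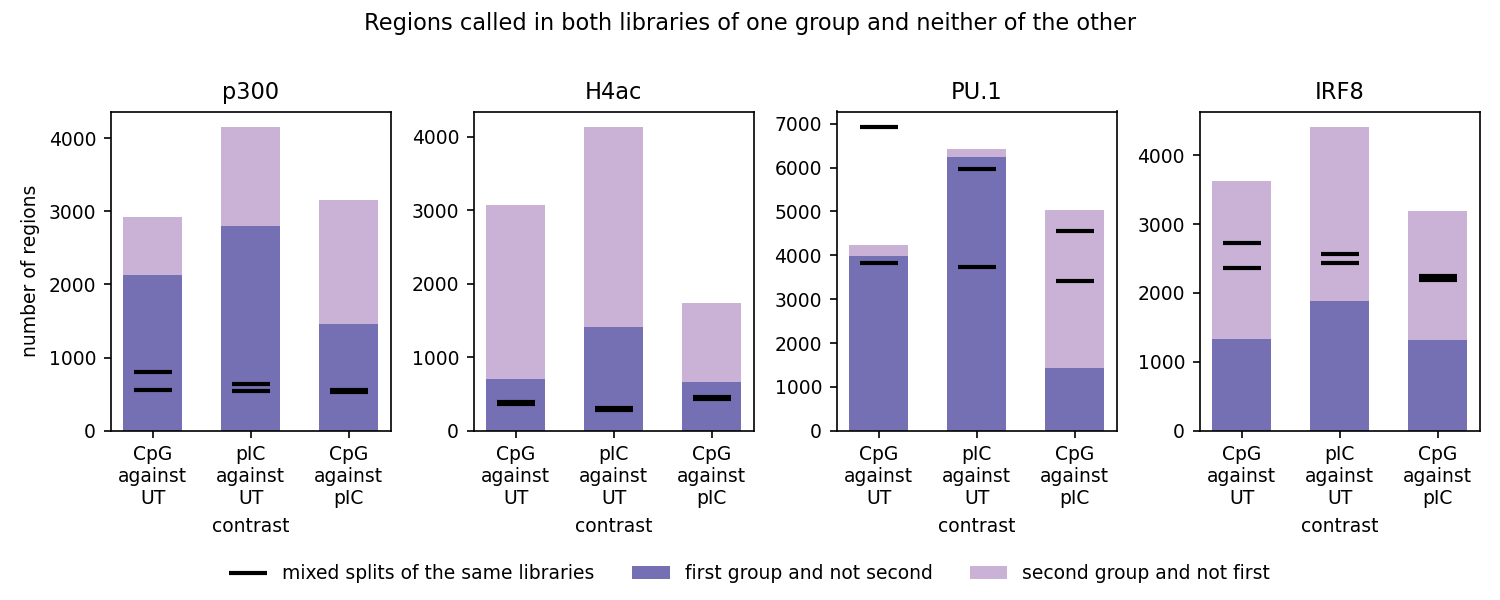
Number of regions called in both libraries of the first group and neither of the second (dark) and the reverse (light), stacked, per contrast and antibody, with the totals of mixed splits of the same 4 libraries as lines. For p300 after pIC the total was 4155 against at most 645, and for PU.1 after CpG it was 4224 against at most 6931.

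IRF3, the factor activated downstream of TLR3, gave calls at Ifnb1, Cxcl10 and Isg15 that differed between stimuli. The single pIC library had 4 IRF3 peaks within 20 kb of Ifnb1 and the CpG and unstimulated libraries 2 each, Isg15 had 1 after pIC and 0 in the other 2 libraries, and Il1b had 9 after pIC, 1 after CpG and 2 in unstimulated cells. IRF3 regions after pIC and not in unstimulated cells numbered 21081, and after CpG 7339. The leading pIC regions were at the promoters of Ifnb1 (chromosome 4, 88522745 to 88523086, -121 bp, percentile 99.7), the chemokine gene Cxcl10 (chromosome 5, 92348904 to 92349262, -137 bp, 99.6), Ccl5 (chromosome 11, 83530500 to 83530834, -149 bp, 98.9) and Isg15 (98.8), and at Parp14 (99.6), Mx2 (97.8) and the signal transducer gene Stat2 (97.4). Among inflammatory genes Hdc (98.2), Tnip3 (97.2), Marcksl1 (96.9) and Rel (95.4) led. Antiviral genes with a pIC region numbered 57 of 81 (1.54 times), interferon and primary genes 16 of 21 (1.94 times) and inflammatory genes 49 of 63 (1.68 times). After CpG the numbers were 19 of 81 (percentile 62.0), not standing apart, and 26 of 63 (1.87 times). After CpG the leading IRF3 regions were at Cxcl10 (65.2), Rel (64.3), Hdc (61.8) and Trim25 (54.8). Directly against CpG, pIC regions lay near 50 of 81 antiviral genes (1.58 times), and CpG regions near 3 (0.530 times). The pIC set held 45.3% of the regions of the 2 lists and the CpG set 5.26%, so the counts of 50 and 3 cannot be compared directly. Matched on IRF3 regions per gene the pIC call ended at 1.07 times, and the CpG fold was 0.362. IRF3 regions lost after CpG lay near 12 of 63 inflammatory (2.46 times) and 10 of 34 myeloid genes (3.20 times). The first call ended within 100 kb (1.68) and, at a fold no lower, within 5 kb (2.85), and both ended when matched on IRF3 regions per gene (1.16 and 1.46). The pIC list is the longest of the IRF3 lists. Matched on IRF3 regions per gene, a count that holds the tested regions, the antiviral call after pIC ended at 1.06 times, the interferon call at 1.14 times and the inflammatory calls at 1.04 (pIC) and 1.00 (CpG) times. With equal list length the percent of regions of the 2 compared libraries gained after pIC moved from 56.9 to 24.3 and after CpG from 31.4 to 20.03, and in the direct comparison from 45.3 to 22.0 for pIC and from 5.26 to 21.6 for CpG.

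IRF5, a factor tied to inflammatory cytokine genes, gained 26898 regions after CpG and 28492 after pIC in single libraries. With lists of equal length the lost percent of regions moved from 18.8 to 33.2 (CpG) and from 17.1 to 32.2 (pIC). Il12b had 6 IRF5 peaks within 20 kb after each stimulus and 2 in unstimulated cells, and Ifnb1 had 3 after CpG, 4 after pIC and 0 in unstimulated cells. Inflammatory genes with a gained region numbered 50 of 63 after CpG (1.53 times) and 49 of 63 after pIC (1.42 times). Regions after CpG and not pIC lay near 11 of 20 pDC and cDC2 markers (3.07 times), which kept the call at 2.29 times when matched on IRF5 regions per gene and lost it with lists of equal length (1.51 times). All other IRF5 list calls ended under that matching, with the inflammatory ones at 1.11 (CpG) and 1.05 (pIC) times.

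IRF8, the lineage factor of this dendritic cell type, gained 1330 regions after CpG and lost 2293, a sum of 3623 against at most 2730 in mixed splits, and after pIC it gained 1888 and lost 2524 (4412 against 2570). With lists of equal length the percent gained after CpG moved from 1.83 to 2.97. Il6 and Il1b had many IRF8 peaks already in unstimulated cells, 6 and 8 for Il6 and 5 and 6 for Il1b. New regions after CpG lay near 15 of 63 inflammatory genes (6.74 times), led by the chemokine genes Cxcl16 (chromosome 11, 70475468 to 70475909, -15652 bp, percentile 56.6), Ccl3 (chromosome 11, 83649336 to 83649882, promoter, -231 bp, 50.2) and Ccl4 (48.6) and by Il1b (51.8). Feedback regulators (6 of 28, 6.04 times), maturation genes (6 of 36, 4.60 times) with Cd83 (63.6) and Adora2a (43.8), and cDC1 genes (5 of 32, 3.72 times) also stood apart. After pIC, 11 of 63 inflammatory genes (3.35 times) and 10 of 32 cDC1 genes (5.12 times) had a new region, with Tnip3 (64.6) and Nfkb1 at its promoter (chromosome 3, 135691395 to 135691601, 41 bp, 63.4) ranked first among inflammatory genes. Regions of IRF8 in CpG and not pIC libraries lay near 7 of 34 myeloid genes (4.24 times). Myeloid genes also stood apart for IRF8 regions in unstimulated and not pIC libraries (2.91 times). The direct comparison thus does not separate gain after CpG from loss after pIC. Matched on IRF8 regions per gene the inflammatory call after CpG held at 3.62 times, while the cDC1 call after CpG (1.61) and the inflammatory call after pIC (2.04) ended. The myeloid calls for CpG, not pIC (2.07), and UT, not pIC (1.56), ended too. The cDC1 call after pIC ended with lists of equal length (2.51 times) and within 5 kb (3.42 times). The cDC1 call after CpG ended with lists of equal length (2.27), within 5 kb (1.75) and with repeats removed (3.54). The maturation call (3.59) and the myeloid call for CpG, not pIC (3.73), ended within 5 kb.

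The IRF8 lists also depended on single libraries. Without unstimulated replicate 1 the calls of feedback regulators (2.15) and cDC1 genes (1.58) after CpG and of inflammatory (1.35) and cDC1 genes (1.94) after pIC ended, and the inflammatory and maturation folds after CpG were 2.27 and 2.87. Without CpG replicate 1 the feedback (2.32) and maturation (1.81) calls after CpG ended, and the inflammatory fold was 4.33. Without CpG replicate 2 the inflammatory, feedback and maturation folds after CpG were 3.91, 2.91 and 2.51. The cDC1 fold after pIC was 2.44 and 2.89 without pIC replicates 1 and 2. The myeloid fold for CpG and not pIC was 2.41 without CpG replicate 1 and 2.53 and 2.54 without pIC replicates 1 and 2.

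PU.1, a myeloid lineage factor that binds widely, gained 3986 regions after CpG and 6245 after pIC, and lost 238 and 167. After CpG the sum of 4224 lay below the highest mixed split, 6931, and after pIC 6412 stood against 5977. Without the unstimulated replicate of 75315 peaks, 34.1% of the regions of the compared libraries counted as gained after CpG. With lists of equal length the percent gained after pIC moved from 6.55 to 4.12, and the percents lost from 0.262 to 2.08 (CpG) and from 0.175 to 2.49 (pIC). New regions lay near 26 of 63 inflammatory genes after CpG (3.86 times) and 27 of 63 after pIC (2.65 times), led after CpG by Ccl4 at its promoter (chromosome 11, 83662236 to 83662557, -179 bp, percentile 73.1), the adhesion gene Icam1 (71.9), Cflar (70.4) and Nfkb1 (62.7), and after pIC by Nfkb1 (80.8), Cflar (77.3), Tnip3 (68.8) and Ccl4 (68.3). After pIC immediate early genes (13 of 26, 2.79 times), feedback regulators (11 of 28, 2.43 times) and maturation genes (13 of 36, 2.21 times) stood apart, and after CpG immediate early genes (9 of 26, 2.87 times). Matched on PU.1 regions per gene both inflammatory calls held at 2.39 (CpG) and 1.69 (pIC) times. The feedback and maturation calls and the immediate early call after CpG ended under a count that includes the tested regions. At equal list length the maturation (1.96) and immediate early calls (1.49 after CpG, 1.2006 after pIC) ended, while the feedback fold rose to 3.2002 and missed the threshold (percentile 98.1). Within 5 kb the maturation (1.92) and immediate early (CpG, 2.63) folds fell little but missed the threshold, and the feedback fold turned to 0.822.

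Each PU.1 list call ended without unstimulated replicate 2. The folds were then 1.198 (CpG) and 1.14 (pIC) for inflammatory genes, 1.19 (CpG) and 1.04 (pIC) for immediate early genes, 1.15 for feedback regulators and 1.09 for maturation genes. The immediate early call after CpG ended also without CpG replicate 1 (1.63) or 2 (1.89), and that after pIC (1.603 and 1.67) and the maturation call (1.59 and 1.605) without pIC replicate 1 or 2. The inflammatory fold after CpG was 2.26 and 2.52 without CpG replicates 1 and 2.

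H4ac, a mark of active chromatin, gained 712 windows after CpG and lost 2363 (3075 against at most 394 in mixed splits). After pIC 1409 were gained and 2729 lost (4138 against 308). The unstimulated lists were the longest, and with lists of equal length the percent gained moved from 3.73 to 8.57 after CpG and from 7.01 to 11.3 after pIC. With the upper 50% of each list it was 5.61 after CpG. Ifnb1 had 2 H4ac windows within 20 kb in each pIC library and 0 in all CpG and unstimulated libraries. Of the interferon and primary genes, 5 of 21 gained H4ac after pIC (4.66 times), with the Ifnb1 promoter (chromosome 4, 88522505 to 88523577, -211 bp, percentile 91.1), Cxcl11 (61.1), Ifna2 (35.9) and Ifna5 (23.7) leading, and this call ended with lists of equal length (3.45 times), within 100 kb (3.30 times) and without pIC replicate 2 (3.46 times). Ifnb1 and Ifna2 lie near each other on chromosome 4, while random lists draw genes singly. Neighbouring genes may thus raise the folds of this list, here and in the direct comparison. The same limit applies to the other lists that hold neighbouring genes, and to their p300 folds. The highest ranked antiviral windows after pIC were at Bst2 (chromosome 8, 71537508 to 71538588, promoter, -571 bp, 99.7), Oas3 (93.9), Pml (89.2) and Ifi47 (85.6), and antiviral genes did not stand apart. Windows lost after CpG lay near 14 of 63 inflammatory genes (2.77 times), led by the NF-kB cofactor gene Bcl3 (chromosome 7, 19823215 to 19824262, promoter, -960 bp, 95.3), Icam1 (92.9), Cflar (88.8) and Lta (85.6), and near 13 of 36 maturation genes (4.35 times), led by Serpinb6b (96.4), Poglut1 (92.0), Tnfsf9 (81.7) and Cd86 (77.3). Windows lost after pIC lay near 9 of 36 maturation genes (2.54 times), a call that ended with lists of equal length (1.84 times) and when matched on H4ac regions per gene (2.16 times). In the direct comparison, pIC windows lay near 5 of 21 interferon and primary genes (7.36 times, 4.204 to 7.38 with 1 library left out, lowest without pIC replicate 1), a call kept when matched on H4ac regions per gene (6.82), and near 6 of 36 maturation genes (4.24 times), with Cd40 at 96.0 and Ccr7 at 71.4, and the fold was 2.78 without CpG replicate 2. Promoters made up 11.3% of windows lost after CpG (Wilson interval 10.1 to 12.7) and 51.0% of those called in all libraries (49.9 to 52.1). The share was also low in the other H4ac sets of the contrasts, from 10.6% (pIC, not CpG) to 22.9% (CpG, not UT). It was 28.3% over all H4ac regions, so a low share is not particular to loss after CpG.

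The last comparison asks which factors lay at the p300 regions of each stimulus. Of p300 regions gained after pIC, 91.4% (Wilson interval 90.3 to 92.4) overlapped an IRF3 peak of the pIC library and 19.2% one of the unstimulated library. Of those gained after CpG, 46.8% overlapped an IRF3 peak of the CpG library and 95.8% an IRF5 peak of the CpG library. IRF5 peaks after pIC overlapped 89.6% of the p300 regions gained after pIC, and unstimulated IRF5 peaks 30.7% and 27.2% of the CpG and pIC sets. IRF3 peaks after pIC overlapped 92.2% of the p300 regions called after pIC and not CpG, and 69.4% of the reverse set. For regions called in all libraries the IRF3 pIC share was 96.4%. IRF8 peaks of matching libraries covered 92.7 and 91.1% of CpG-gained and 92.3 and 93.5% of pIC-gained p300 regions, and unstimulated IRF8 peaks covered 77.4 and 69.9% of the CpG-gained set. PU.1 peaks after CpG covered 92.1 and 91.3% of the CpG-gained set, and PU.1 peaks after pIC 86.2 and 86.5% of the pIC-gained set. H4ac windows of the pIC libraries covered 28.3 and 30.5% of p300 regions called after pIC and not CpG, and 10.2 and 10.1% of the reverse set. List length differs between libraries, and a longer list overlaps more regions.

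**Figure D5:**
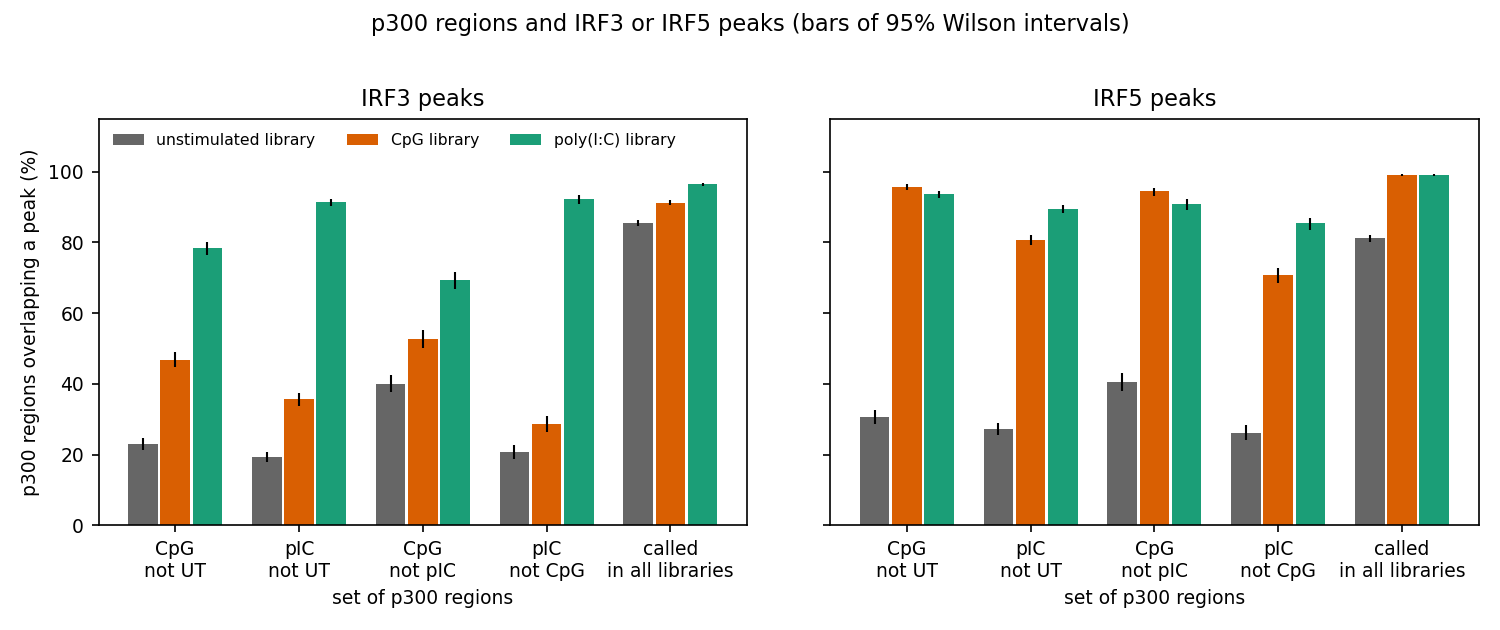
Percent of p300 regions in 5 sets that overlap an IRF3 (left) or IRF5 (right) peak of the unstimulated, CpG or pIC library, with 95% Wilson intervals. IRF3 peaks after pIC overlap 91.4% of p300 regions gained after pIC, and IRF3 peaks after CpG overlap 46.8% of those gained after CpG.

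Housekeeping genes near gained p300 regions numbered 4 of 31 after CpG and 5 of 31 after pIC, T and B cell markers 1 and 2 of 16, macrophage, monocyte and neutrophil markers 0 and 1 of 25, pDC and cDC2 markers 4 and 5 of 20, antigen presentation genes 4 and 7 of 33, and genes of non-haematopoietic tissues 2 and 0 of 33. Toll-like receptor signalling genes numbered 6 and 3 of 33. None of these lists stood apart for p300 regions gained after CpG or pIC. The 4 lists of housekeeping genes, other tissues, T and B cells, and macrophages, monocytes and neutrophils passed the 99th percentile in 0 of 144 percentiles, while 66 of all 540 did. Irf8, the lineage factor gene, had 1 p300 peak within 20 kb in each of the 6 libraries, and Spi1, which encodes PU.1, 2 or 3. Ifit1 had 0 peaks in all libraries but 1 of H4ac, since the peak at its TSS was assigned to another gene in the annotation, which is a limit of nearest-gene names. Libraries labelled cREL had 16834 (CpG), 15444 (pIC) and 12302 (unstimulated) peaks, and those labelled JUNB had 15355, 249 and 4368.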

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

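The test of the shared peaks of the lists labelled cREL pIC and JUNB CpG and the 3 tests of low-complexity sequence were chosen after the results were seen, and the test of the list labelled cREL UT before.

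Of the p300 regions called after pIC and not CpG, 13.2% (224 of 1694) lay in low-complexity sequence by the repeat column, which the comparisons do not use, against 0.62% of the reverse set. The p300 lists held 2.19 and 2.22% such peaks after pIC, 0.518 and 0.624% after CpG and 0.668 and 0.821% in unstimulated cells, and IRF3 held 1.90% after pIC against 0.373 and 0.292% in its other lists. A preparation effect shared by all pIC samples was argued against by PU.1, whose lowest pIC share minus its highest CpG share was -0.0796 percentage points. IRF8 (1.62 and 1.63% after pIC, 1.41 and 1.34% after CpG) and IRF5 (1.20 and 0.956%) went the other way, so an effect in some of the samples stays open. Unstimulated lists held 1.28 and 1.38% for IRF8 and 1.29% for IRF5, so the IRF5 share was not highest after pIC. A mapping background stays open too, since the overlap of 0% of the 224 regions with input peaks decides nothing where the 6 input lists hold 1 low-complexity peak. The biological explanation tested, purine runs that hold IRF sites, goes with A-rich, T-rich, GA-rich or CT-rich sequence in 9.09% of the pIC set (154 regions) and 0.48% of the CpG set. It also goes with IRF3 peaks after pIC at 97.8% of the 224 regions (91.4% of the others). IRF5 (73.7 against 87.2%), IRF8 (85.7 and 84.8 against 91.5 and 93.1%) and PU.1 (40.2 and 42.0 against 86.8 and 87.3%) overlapped them less. G-rich or C-rich sequence made up 3.96 and 0.07% of the pIC and CpG sets. The test assumed that such sequence holds few of these runs, and by that rule it went against the explanation for this part. No sequence was read, so the assumption was not checked and the explanation stays open.

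Of the peaks in the library labelled JUNB pIC, 56.7% overlapped input peaks, and the next highest ChIP list, p300 in unstimulated cells, had 2.98%. It holds 249 peaks, its peak names give unstimulated cREL, so it is 1 of the 4 lists in conflict with their labels, and no explanation was tested.

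The lists labelled cREL pIC and JUNB CpG shared 66.3% of their regions (Jaccard index), while the highest index of the first with another list labelled cREL was 46.5%. The names inside both files give JUNB, and 4 of the 6 cREL and JUNB lists carry such a conflict. This index was seen before its test was written, so it is no independent test of lists attached to the wrong sample record. The reverse, that labels are right and the names wrong, was argued against by the list labelled cREL UT. Its mean index with unstimulated p300 lists was 29.2 against 40.5 with stimulated ones, a difference of -11.3. The single indices were 29.7 and 28.7 with unstimulated lists and 40.3 to 40.8 with stimulated ones. The planned yardstick, an SD of 5.85 over all p300 lists, spans both groups, so it holds the difference itself and does not measure noise. No biological explanation was tested, and the stimuli of the first 2 lists and the record of the list labelled JUNB pIC stay open.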

How the results depend on the processing

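Matching on regions of the antibody itself, removal of low-complexity and simple repeats, and the libraries left out in turn for gene lists, peak numbers and shared regions were tests chosen after the results were seen, and the other alternatives were fixed before. Overlap of at least 50% of the shorter peak, removal of peaks at input peaks (at most 2.98% of a list of these antibodies) and removal of repeats kept all 36 gained and lost results within 1.5 times their value, as percents of the regions of the libraries compared. With the upper 50% of each list by score 34 of 36 did, and the others were H4ac CpG, not UT (5.61% of regions) and PU.1 UT, not pIC (0.267%). With lists of equal length, where regions gained after both were also recounted, 23 of 42 did. The rest were, in percent of regions and each against its value with full lists, for H4ac 8.57 against 3.73 (CpG, not UT), 11.3 against 7.01 (pIC, not UT) and 4.99 against 2.21 (gained after both), for IRF8 2.97 against 1.83 (CpG, not UT) and 1.24 against 0.792 (gained after both), for PU.1 2.08 against 0.262 (UT, not CpG), 2.49 against 0.175 (UT, not pIC) and 4.12 against 6.55 (pIC, not UT), and for p300 8.17 against 4.03 (UT, not CpG) and 11.05 against 6.57 (UT, not pIC). For IRF3 they were 20.03 against 31.4 (CpG, not UT), 19.9 against 10.8 (UT, not CpG), 24.3 against 56.9 (pIC, not UT), 23.9 against 2.79 (UT, not pIC), 21.6 against 5.26 (CpG, not pIC), 22.0 against 45.3 (pIC, not CpG) and 6.44 against 14.5 (gained after both), and for IRF5 33.2 against 18.8 (UT, not CpG) and 32.2 against 17.1 (UT, not pIC). Single lists of equal length hold nearly as many regions apart on each side by construction, and for the replicated antibodies the cause was not tested.

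Leaving out a library relaxes the call from 2 libraries to 1, which raises the percents by construction. For p300 they were 10.8 to 23.4 (CpG, not UT), 4.04 to 19.98 (UT, not CpG), 13.6 to 25.4 (pIC, not UT), 6.57 to 23.5 (UT, not pIC), 7.48 to 16.3 (CpG, not pIC), 8.68 to 16.7 (pIC, not CpG) and 4.97 to 10.3 (gained after both). For H4ac they were 3.73 to 7.87 (CpG, not UT), 12.4 to 24.6 (UT, not CpG), 7.03 to 11.7 (pIC, not UT), 13.6 to 25.3 (UT, not pIC), 3.95 to 9.98 (CpG, not pIC), 6.44 to 12.8 (pIC, not CpG) and 2.48 to 3.72 (gained after both). For PU.1 they were 4.40 to 34.1 (CpG, not UT), 0.263 to 12.1 (UT, not CpG), 6.55 to 37.4 (pIC, not UT), 0.175 to 9.84 (UT, not pIC), 1.497 to 8.40 (CpG, not pIC), 3.73 to 13.0 (pIC, not CpG) and 2.29 to 23.5 (gained after both). For IRF8 they were 1.83 to 6.96 (CpG, not UT), 3.15 to 15.05 (UT, not CpG), 2.54 to 8.36 (pIC, not UT), 3.40 to 14.5 (UT, not pIC), 1.89 to 6.78 (CpG, not pIC), 2.69 to 8.60 (pIC, not CpG) and 1.03 to 3.52 (gained after both). The highest PU.1 percents gained after CpG and pIC came without unstimulated replicate 2, and the highest percents lost without replicate 1. The log2 ratio of peak number ranged over -0.15 to 0.50 (CpG against UT), -0.16 to 0.49 (pIC against UT) and -0.040 to 0.059 (CpG against pIC) for p300, -0.13 to 1.16 and -0.015 to 1.28 for PU.1 and -0.25 to 0.056 and -0.21 to 0.097 for IRF8 against UT. The sign turned for p300 without unstimulated replicate 2 (-0.15 and -0.16) and, between CpG and pIC, without CpG or pIC replicate 1 (lowest -0.040), for PU.1 without unstimulated replicate 1 (-0.13 and -0.015) and for IRF8 without unstimulated replicate 1 (0.056 and 0.097). The fold over random lists of the p300 antiviral list after CpG ranged over 1.77 to 2.19 and that of the inflammatory list for pIC, not CpG, over 1.59 to 2.45. In the replicate block of same-numbered libraries, which share only a number, the log2 ratio was 0.18 for p300 CpG against UT and -0.31 for H4ac CpG against UT, as without the block, and no call was possible, since the smallest p of 2 pairs is 0.5. The correlation of deviations between same-numbered libraries lay between -0.01 and 0.03.

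For gene lists, the p300 antiviral list after CpG passed the threshold within 5 kb (2.76 times) and without matching (2.92 times), as did the p300 inflammatory list for pIC, not CpG, without matching (3.07 times). Without repeats the p300 antiviral list after pIC held at 3.41 times, and for pIC, not CpG, at 4.77 times. The main matching puts 9560 of 20290 genes in its highest class, so main folds may in part reflect the number of regions near a gene. Matching on regions of the antibody counts the tested regions too and lowered 71 of 72 list folds, so a call lost under it was not read as absence of an excess. The calls that ended under it were p300 inflammatory CpG, not pIC (1.17), and IRF3 antiviral pIC, not UT (1.06) and pIC, not CpG (1.07), and inflammatory CpG, not UT (1.00) and pIC, not UT (1.04). Called lists whose fold turned below 1 under it were IRF3 inflammatory pIC, not CpG (0.935), cDC1 genes of p300 CpG, not UT (0.911), of IRF3 CpG, not UT (0.971), of IRF5 UT, not CpG (0.994) and pIC, not UT (0.972), and myeloid genes of IRF3 pIC, not UT (0.940) and pIC, not CpG (0.919), and of IRF5 pIC, not UT (0.988). The p300 inflammatory list for pIC, not CpG (0.841), and the IRF3 antiviral list for CpG, not UT (0.742), turned under it too, but neither had a call. The other turns of called lists came within 5 kb, for p300 cDC1 genes after CpG (0.668) and PU.1 feedback regulators after pIC (0.822). The cause of these 2 was not tested. Among lists outside the main questions, 35 of 56 lost their call without a turn under that matching, 16 within 5 kb, 15 with equal list length, 6 within 100 kb and 2 without repeats. With 1 library left out in turn, 26 settings lost the call and 166 did not, the 26 belonging to 16 of 32 lists, and the folds of PU.1 inflammatory genes ranged over 1.198 to 3.97 (CpG) and 1.14 to 2.74 (pIC) and of IRF8 feedback regulators after CpG over 2.15 to 5.93. Overlap of 50% of the shorter peak lowered the share of gained H4ac windows with IRF3 peaks to 17.4% (CpG) and 42.7% (pIC) and with IRF5 peaks to 62.1% (CpG) and 62.7% (pIC), since fewer pairs pass by construction. The motif windows were not run, as no genome sequence was at hand. The depth of each library is unknown, so a region missing from a list may be one below the calling threshold, and PU.1 UT, not pIC, reached 9.84% without unstimulated replicate 1.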

Other observations

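The H4ac tests were written before their results were seen, except for the reading of the window test, the share of the 28 regions near the genes of the pattern and the shares away from promoters.

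H4ac windows lost after CpG lay near 14 inflammatory genes, of which 10 also gained p300, among them Icam1, Lta and Rel, and near 13 maturation genes, of which 5 did, among them Cd40 and Cd86. Longer unstimulated lists were argued against, since 2 of the 2 gene lists stayed above the 99th percentile with lists of equal length. Windows that moved a short way were argued against by the share of lost regions with a CpG window within 2 kb, 2.45% (1 of the 28 near these genes), a reading taken after the planned comparison with regions called in all libraries (0 of 7918) proved void, as the caller keeps windows apart. Loss of acetylation where p300 arrives passed its planned comparison, as 3.005% of lost regions overlapped gained p300 against 1.83% of regions called in all libraries, but promoters are fewer among lost regions, and away from promoters the shares were 2.86% (Wilson interval 2.23 to 3.67) and 2.68% (2.22 to 3.24), so it stays open. Lost p300 regions overlapped 2.92% of all lost H4ac regions against 0.404% (3.15 and 0.722% away from promoters), and most losses touched neither. Of the 28 lost regions near the genes of the pattern, 7 overlapped gained p300 (25%, Wilson interval 12.7 to 43.4) and 0 lost p300. Only 3 regions called in all libraries lay near these genes, too few for a comparison.

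The unstimulated PU.1 replicate 1 list held 413 peaks found in no other PU.1 list, 1.34% of its peaks, and 10.4% of its peaks were at promoters, with no explanation tested. IRF5 peaks were at promoters in 17.7% of cases in unstimulated cells, against 11.5% after CpG and 12.2% after pIC.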
